A study of Homo sapiens with 9 samples.

How the data were processed

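RNA-seq gene tables of 9 libraries of hypoxic MDA-MB-231 cells, 6 labelled sgL1 and 3 labelled sgCtrl, were used. RNA was isolated with TRIzol and libraries followed standard Illumina protocols, per the labels' protocols. The submitters' processing notes name fastp 0.20.1, STAR 2.7.7a and featureCounts 2.0.0 and the human build GRCh38 (hg38). The settings of these tools, the annotation release, any filter and whether counting used the strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The authors deposited a table of whole-number counts per gene, without normalization, and a table of FPKM values. The deposited FPKM equalled the counts multiplied by 1 constant per gene and 1 per sample (largest relative deviation 9.21e-15 among genes with over 100 counts in every library).

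Both tables held 59362 rows named by gene symbol. The 627 rows without a symbol, holding 0.358% to 0.410% of the counts of a library, were left out of library sizes and tests, which left 58735 rows. Another 12 rows with names turned into dates by a spreadsheet, and 1741 rows that share a name, were kept as separate rows but are never named here. Gene type and coordinates were taken from GENCODE release 29 (GRCh38), in which 99.98% of the rows have their symbol; this may not be the release the authors used. Totals on named genes ranged from 15420073 to 17038409, and a count of 0 allows up to 3 counts, or 0.176 to 0.195 CPM. Counts come from PCR-amplified reads with no molecular identifiers named in the labels, so intervals and floors cover counting error only. No 2 libraries of a group were alike within sampling noise: chi-square per gene between pairs ran from 2.39 to 10.5, where about 1 marks noise alone.

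The main test was edgeR 4.0.16 (R 4.3.3) on the counts as deposited: genes kept by filterByExpr, TMM scaling, robust dispersions, quasi-likelihood F test of sgL1 against sgCtrl with all 9 libraries and no covariate, and Benjamini-Hochberg adjusted p under 0.05. Levels are TMM-scaled CPM with their SD, and fold changes are edgeR's, with SE from the F statistic. UFL1 and UFM1 were also compared by an exact two-sided permutation test of mean log2 CPM over the 84 splits. The comparison of sgL1 libraries 1-3 with 4-6 used the same test on these 6 libraries.

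The groups, tests, alternatives for sgL1 against sgCtrl, 32 gene lists and the rule for named genes were set before the data were examined. The lists cover UFMylation, ER, stress, hypoxia, metabolism, inflammation, matrix, adhesion, cell cycle and library quality, and markers of fibroblasts, leukocytes and luminal breast cells; 764 of 766 members were found, 30 of them under another symbol. Lists with at least 5 tested members, 30 in all, were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 30 lists; the call of 20 lists is set beside camera with an estimated correlation and limma's fry test. The calls that hold with an estimated correlation are those of HIF targets, NF-kB genes, matrix genes, YAP/TAZ targets and ER chaperones. The named genes are all measured UFMylation genes, including UFL1 and UFM1, which the design text names. The 12 largest rises and 12 largest falls are named as well. They were taken among protein-coding genes with a unique symbol, adjusted p under 0.05, a mean of at least 1 CPM and no overlap between groups. For each list described, the up to 4 members with the smallest adjusted p are also named. Names outside this rule are marked as chosen after their values were seen.

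The fit was first tested on counts simulated for the 15242 genes with the libraries' own depths and dispersions. For sgL1 against sgCtrl it recovered 38% of 50 genes changed 1.2-fold, 56% of 50 changed 1.5-fold, 70% of 50 changed 2-fold and 94% of 50 changed 3-fold, and 4.44% of the calls were genes simulated without change. The list test called the 1 list raised among 30 simulated lists and 0 of the others. Genes of the simulated lists varied independently, so this does not show how often lists whose members vary together are called falsely.

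Alternatives were RLE, upper-quartile and library-size scaling; DESeq2 1.42.0; limma-voom with quality weights; no expression filter, or 1 CPM in at least 3 libraries; an adjusted p under 0.01; a test against a 1.5-fold change; limma on log2(FPKM + 1) and log2(FPKM + 0.1), and on genes with a mean FPKM of at least 1; each library left out; the replicate number as a block; sgL1 1-3 or 4-6 alone; and 1 surrogate variable (sva 3.50.0). Those run on sgL1 libraries 1-3 against 4-6 (scaling, DESeq2, filters, thresholds and single libraries left out) were chosen after seeing the data. On the FPKM scale a fold change is that of log2(value + pseudocount), which understates changes of low genes. Overlaps between comparisons with the same controls were set beside 20 simulated draws of unchanged groups.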

Results

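Transcript levels were measured by RNA-seq of total RNA in MDA-MB-231, an established line of triple-negative breast cancer cells that lacks oestrogen receptor, progesterone receptor and HER2 amplification. The series title places the cells under hypoxia, a lowered oxygen supply, for 6 h. By genotype label the 9 libraries formed 1 group of 6, sgL1, and 1 group of 3, sgCtrl. The design text names UFL1 and UFM1 as the genes targeted. UFM1 is a small protein that is attached to other proteins, many of them at the endoplasmic reticulum (ER), in a reaction called UFMylation, and UFL1 is the ligase of the last step. The label sgL1 was read as a guide RNA against UFL1 and sgCtrl as a control guide; the labels do not spell this out, and no library is labelled for UFM1. Each library held between 15420073 and 17038409 counts on named genes, so a gene at 20 CPM (counts scaled to library size) carried a counting error of about 5.63%. The typical spread between libraries of a group, the common biological coefficient of variation, was 6.53%. The labels do not say that the libraries came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

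The level of UFL1 was examined first, since it bears on what the label sgL1 means. UFL1 (ENSG00000014123, chromosome 6, 96521595 to 96555276, plus strand, GRCh38, protein-coding) lay below every sgCtrl library in all 6 sgL1 libraries, but at 2 levels. It measured 26.1 ± 1.18 CPM (SD, n = 3) in sgCtrl, 13.7 ± 1.31 CPM (SD, n = 3) in sgL1 libraries 1-3 and 21.4 ± 1.42 CPM (SD, n = 3) in sgL1 libraries 4-6. These means were 52.5% and 82.1% of the sgCtrl mean. Raw counts were 429, 404 and 396 in sgCtrl, 234, 208 and 204 in sgL1 libraries 1-3, and 383, 339 and 332 in libraries 4-6. Over all 6 libraries the log2 fold change was -0.57 (SE 0.20), which did not pass edgeR's quasi-likelihood test (adjusted p = 0.126); the exact two-sided permutation test of log2 CPM over all 84 splits gave p = 0.0238, where 0.0119 is the smallest value possible. Against sgCtrl, libraries 1-3 alone gave -0.93 (edgeR adjusted p = 1.24e-08) and libraries 4-6 alone -0.28 (edgeR adjusted p = 0.0145). The series title calls the cells a knockdown and the design text a knockout, and messenger RNA need not fall after a knockout, so these levels do not measure the loss of the protein.

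**Figure D1:**
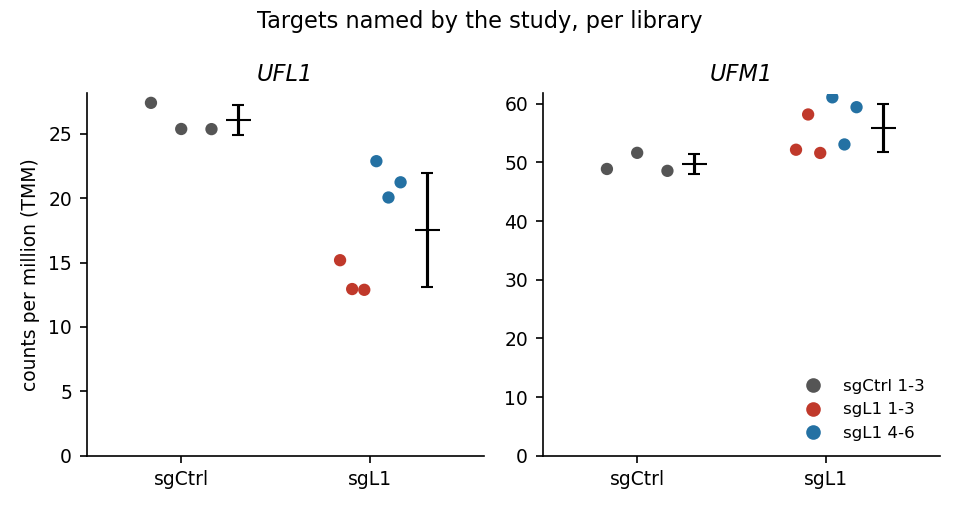
CPM (TMM-scaled, vertical axis from 0) of UFL1 and UFM1 in each library, by group; points are libraries, coloured by sgCtrl, sgL1 1-3 and sgL1 4-6, and the black bars give the mean and SD of each group. UFL1 lies at 13.7 CPM on average in sgL1 1-3 and at 21.4 CPM in sgL1 4-6, against 26.1 CPM in sgCtrl, whereas UFM1 lies slightly above sgCtrl.

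None of the 9 UFMylation genes measured passed edgeR's test over all libraries after adjustment, which 1447 of the 15242 genes tested passed. Of the 9, UFM1, DDRGK1 and UFL1 were among the 3272 genes with an unadjusted p under 0.05 in edgeR's test. UFM1 (chromosome 13, 38349849 to 38363619) measured 55.9 ± 4.12 CPM (SD, n = 6) in sgL1 and 49.7 ± 1.69 CPM (SD, n = 3) in sgCtrl, a log2 fold change of 0.17 (SE 0.06; edgeR adjusted p = 0.0862; exact two-sided permutation p = 0.0357). DDRGK1, which anchors UFL1 at the ER membrane, gave 0.29 (edgeR adjusted p = 0.116). The E2 enzyme UFC1 gave 0.13, CDK5RAP3 -0.10, ODR4 0.04, and the proteases UFSP1 and UFSP2 0.03 and 0.04. As a list these genes did not stand apart (camera adjusted p = 0.711); their median was 0.04 and their mean -0.002, which differ in sign. Adjusted over the list alone, 0 of the 9 genes passed.

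Between sgL1 and sgCtrl, 841 genes rose and 606 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, 15242 genes tested). Most changes were small: 84 genes rose and 25 fell at least 2-fold. Of the 1447 genes, 1361 are protein-coding, and 1292 had no overlap between the sgL1 and the sgCtrl libraries; 14.01% of all tested genes had none, where chance gives 2.38%. The first principal component, with 23.8% of the variance, separated sgCtrl from sgL1, and the second, with 14.1%, separated sgL1 libraries 1-3 (5.37 to 19.7) from 4-6 (-19.6 to -5.51), with sgCtrl between -4.63 and 3.47. Without sgCtrl 1 or sgCtrl 2 the number that rose was 548 and 549; without sgCtrl 1, 2 or 3 the number that fell was 400, 352 and 385.

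Among the 12 largest rises were cytokine, complement and chemokine genes. IL1B, the cytokine interleukin-1 beta (chromosome 2, 112829751 to 112836903), rose 14.8-fold, from 2.31 ± 0.126 CPM (SD, n = 3) to 34.4 ± 12.1 CPM (SD, n = 6; edgeR adjusted p = 0.00167). CSF3, the granulocyte growth factor G-CSF (chromosome 17, 40015361 to 40017813), rose 12.2-fold, from 5.79 ± 0.204 to 70.8 ± 3.87 CPM (edgeR adjusted p = 8.63e-23). The complement component C3 (chromosome 19, 6677704 to 6730562) rose 7.21-fold, from 40.0 ± 1.72 to 288.3 ± 13.2 CPM (edgeR adjusted p = 9.77e-25), and PTGS2, the prostaglandin-forming cyclooxygenase COX-2 (chromosome 1, 186671791 to 186680427), rose 5.49-fold to 81.5 ± 2.75 CPM. C15orf48 (log2 fold change 2.53), the phospholipase gene PLA2G4D (2.07), the matrix protease stromelysin MMP3 (2.03), the IL-13 decoy receptor IL13RA2 (1.97), DEPP1 (1.92) and the neutrophil-attracting chemokines CXCL3 (1.87) and CXCL1 (1.84) completed the 12 largest rises together with SPP1. SPP1, which encodes osteopontin, had a log2 fold change of 2.41 with an edgeR adjusted p of 0.0256 that went to between 0.101 and 0.115 without sgCtrl 1, 2 or 3. All 12 were higher in 6 of 6 sgL1 libraries, which the rule of no overlap between groups required.

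Of 22 tested NF-kB inflammatory genes, a fixed list of genes switched on by that transcription factor, 15 rose and 1 fell (median log2 fold change 0.43; camera adjusted p = 6.78e-45, and adjusted p = 3.06e-05 with an estimated correlation). Adjusted over the list alone, 16 rose and 2 fell. PTGS2 (2.46), CXCL1 (1.84), CXCL8 (1.46) and CXCL3 had the smallest adjusted p-values. The gene that fell was BIRC3 (-0.30), an inhibitor of apoptosis; it was named after its value was seen. CXCL1 and CXCL3 are close paralogs, and reads that fit both could be split between them by the counting.

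**Figure D2:**
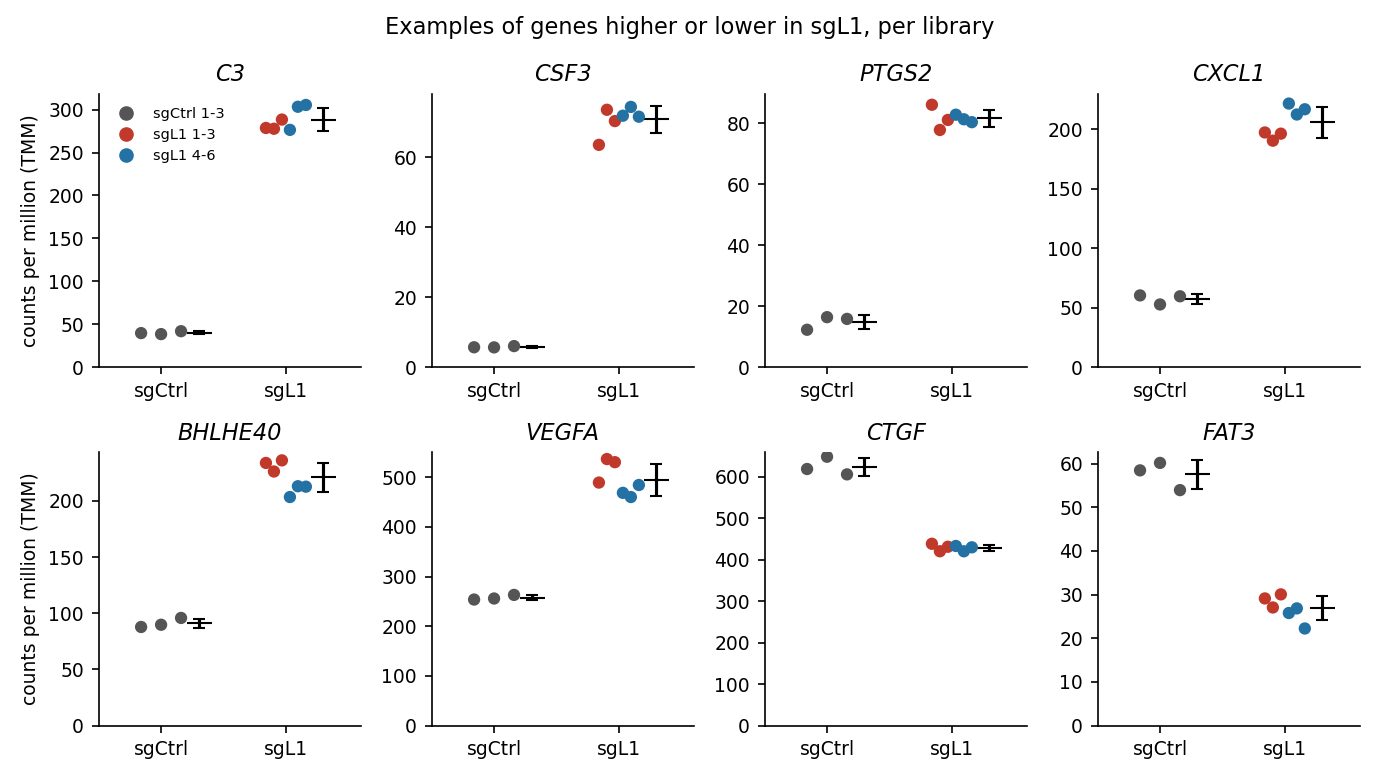
CPM (TMM-scaled, vertical axes from 0) of 8 genes in each library, with points coloured by sgCtrl, sgL1 1-3 and sgL1 4-6 and black bars for the mean and SD of each group. C3, CSF3, PTGS2, CXCL1, BHLHE40 and VEGFA lie above sgCtrl in all 6 sgL1 libraries, and CTGF and FAT3 lie below.

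Genes induced by hypoxia-inducible factors (HIF) were higher in sgL1 although both groups were under hypoxia. Of 37 tested HIF targets 36 rose and 0 fell (median 0.44, camera adjusted p = 2.68e-94, and adjusted p = 8.17e-04 with an estimated correlation), and the count was also 36 adjusted over the list alone. The transcription factor BHLHE40 (chromosome 3, 4979116 to 4985323) rose from 91.2 ± 4.19 to 220.9 ± 13.1 CPM, a log2 fold change of 1.28 (SE 0.05; edgeR adjusted p = 1.09e-16). PFKFB3, a regulator of glycolysis, rose by 0.97, VEGFA, which drives vessel growth, by 0.94, and the glucose transporter SLC2A3 by 0.90. No library without hypoxia was analysed here, so the size of the hypoxic response itself was not measured. Among 12 tested components of the HIF pathway, EGLN3 (0.93), EGLN1 (0.37) and EPAS1 (0.17) rose and CITED2 (-0.41), a negative regulator of HIF, fell. EGLN1 and EGLN3, the oxygen-sensing prolyl hydroxylases, are HIF targets as well and stand on both lists. The EPAS1 call was lost with 7 of the 9 libraries left out in turn and with upper-quartile scaling. The list of components was not called (camera adjusted p = 0.317, median -0.01, mean 0.06); adjusted over the list alone, 3 rose and 2 fell.

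Of 18 tested glycolysis genes, 11 rose and 0 fell (median 0.21, camera adjusted p = 3.38e-11; adjusted p = 0.0797 with an estimated correlation). Adjusted over the list alone, 15 rose. The enzymes PGK1 (0.31), HK2 (0.44), LDHA (0.27) and HK1 (0.30) had the smallest adjusted p-values, and LDHA reached 1757 ± 20.9 CPM in sgL1 against 1459 ± 8.14 CPM in sgCtrl. HK2 also stands on the list of HIF targets. Nuclear-encoded oxidative phosphorylation moved little: 2 of 45 genes rose, COX4I1 (0.16) and NDUFA1 (0.32), and 0 fell (median 0.07, camera adjusted p = 0.0412; adjusted p = 0.492 with an estimated correlation). The COX4I1 call was lost without sgCtrl 2 or sgCtrl 3 and the NDUFA1 call with 5 of the 9 libraries left out in turn, and adjusted over the list alone 1 gene rose.

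Genes of the extracellular matrix and of mesenchymal cells went both ways. Of 34 tested members 21 rose and 6 fell (median 0.26, camera adjusted p = 1.97e-16, and adjusted p = 0.00229 with an estimated correlation); adjusted over the list alone, 22 rose and 7 fell. The matrix glycoprotein TNC rose by 0.93, from 80.2 ± 2.02 to 152.6 ± 8.93 CPM. The urokinase receptor PLAUR rose by 0.63 and the membrane-bound protease MMP14 by 0.60. CTGF was among the members that fell.

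The targets of YAP and TAZ, transcriptional coactivators that respond to cell shape and density, fell together. Of 18 tested members 14 fell and 0 rose (median -0.26, camera adjusted p = 6.68e-21, and adjusted p = 0.00145 with an estimated correlation); adjusted over the list alone, 14 fell and 1 rose. CTGF (chromosome 6, 131948176 to 131951373, now named CCN2) went from 623.9 ± 21.8 CPM to 428.7 ± 7.21 CPM, a log2 fold change of -0.54 (SE 0.04; edgeR adjusted p = 4.77e-12). ANKRD1 went from 1203 ± 18.3 CPM to 827.5 ± 37.3 CPM (-0.54), the growth factor TGFB2 had -0.73 and CRIM1 -0.38. Among 10 tested epithelial genes the keratins KRT7 (-0.26) and KRT8 (-0.21) fell and 0 rose (median -0.08, camera adjusted p = 0.0340; adjusted p = 0.380 with an estimated correlation); adjusted over the list alone, 2 fell.

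**Figure D3:**
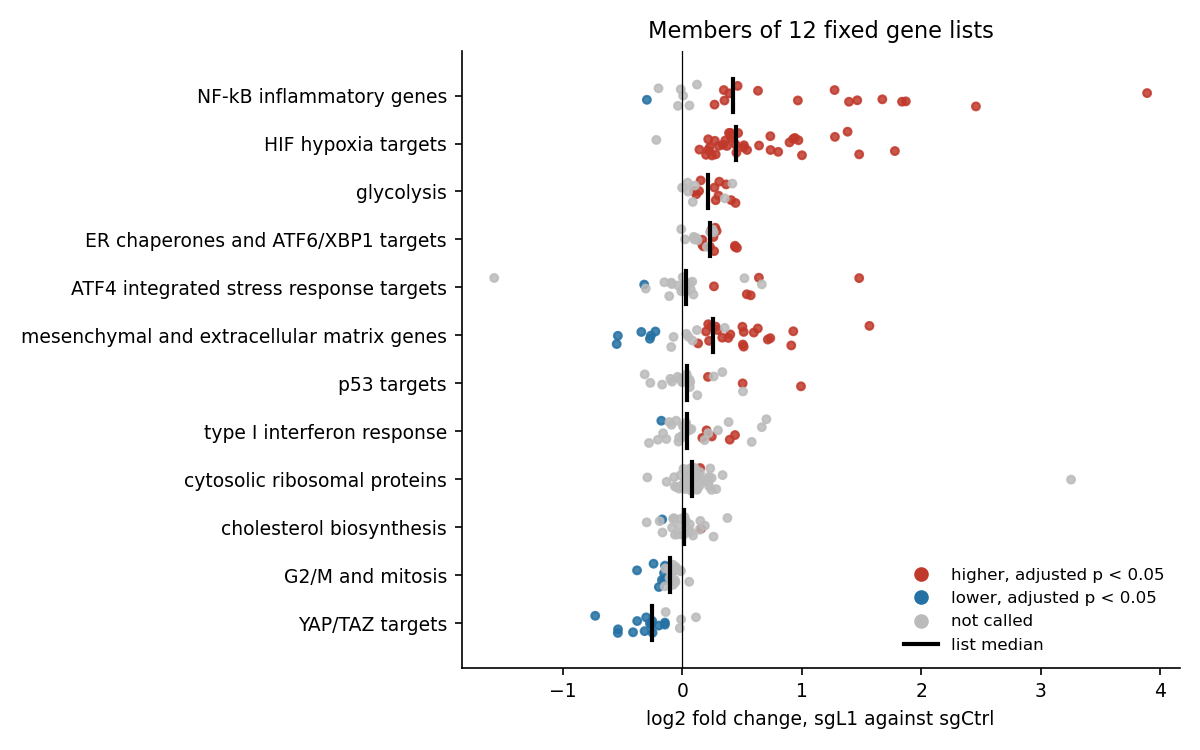
Log2 fold changes of sgL1 against sgCtrl (horizontal axis) for each tested member of 12 of the fixed gene lists, 1 point per gene; red and blue points passed edgeR's test as higher or lower, grey points did not, and black bars mark the list medians. HIF targets (median 0.44) and NF-kB genes (0.43) lie to the right and YAP/TAZ targets (-0.26) to the left.

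Genes of ER protein folding rose by small amounts. Of 23 tested ER chaperones and targets of the stress regulators ATF6 and XBP1, 13 rose and 0 fell (median 0.23, camera adjusted p = 2.82e-11, and adjusted p = 0.00807 with an estimated correlation); adjusted over the list alone, 20 rose. XBP1, itself a regulator of the unfolded protein response, rose by 0.44 (SE 0.05; edgeR adjusted p = 7.68e-07), the COPII coat protein SEC24D by 0.46, and the chaperones PDIA4 and HSPA5 by 0.29 and 0.26. HSPA5, known as BiP, reached 955.4 ± 41.7 CPM in sgL1 against 795.2 ± 18.4 CPM in sgCtrl.

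Other ER lists moved less, and none of them was called with an estimated correlation. In ER-associated degradation, 6 of 19 genes rose and 0 fell (median 0.11, camera adjusted p = 0.00945; adjusted p = 0.0696 with an estimated correlation), among them EDEM1 (0.23), OS9 (0.24), UFD1 (0.22) and MAN1B1 (0.22). Of 30 genes of the signal recognition particle, translocon and oligosaccharyltransferase, 7 rose and 0 fell (median 0.09). Its camera adjusted p was 0.00102, and 0.0894 with an estimated correlation. SEC11A (0.25), STT3A (0.17), SRPRA (0.16) and DAD1 (0.19) were among those that rose. SRPRA lost its call without sgCtrl 1 (edgeR adjusted p = 0.0636). DAD1 lost its call without sgCtrl 2, sgCtrl 3, sgL1 1 or sgL1 5. In ER-Golgi transport, SEC24D, LMAN1 (0.18), TMED10 (0.14) and GOLGA2 (0.23) rose and 0 of 28 fell (median 0.07, camera adjusted p = 0.00256; adjusted p = 0.0615 with an estimated correlation). Adjusted over each list alone, 6, 11 and 8 genes rose. Of 25 targets of ATF4, the effector of the integrated stress response, 5 rose and 1 fell (median 0.03, camera adjusted p = 0.00704; adjusted p = 0.1002 with an estimated correlation); adjusted over the list alone, 7 rose and 2 fell. DDIT4 (1.48), CEBPB (0.57), VLDLR (0.54), ATF4 (0.26) and CHAC1 (0.64) rose, while SLC7A11 (-0.32), the cystine transporter, fell; DDIT4 is a HIF target too, and CHAC1 was named after its value was seen. Some of these calls rested on single libraries: UFD1 was lost without sgCtrl 3 (adjusted p = 0.0842), MAN1B1 without sgCtrl 2 (0.155), LMAN1 without sgCtrl 1 (0.145), TMED10 without any 1 of the 3 sgCtrl libraries and GOLGA2 with 7 of the 9 libraries left out in turn.

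In ER-phagy and autophagy, GABARAPL1 (0.61), ULK1 (0.28), NBR1 (0.15) and MAP1LC3B (0.15) rose and 0 of 19 genes fell (median 0.15, camera adjusted p = 0.0255; adjusted p = 0.0894 with an estimated correlation). In the lysosome list GLA (0.33), CTSL (0.18), LAMP1 (0.16) and ATP6AP1 (0.21) rose and 0 of 25 fell (median 0.10, camera adjusted p = 0.0172; adjusted p = 0.111 with an estimated correlation). Adjusted over each list alone, 6 and 6 genes rose. Of these 8 genes, GABARAPL1 and GLA kept their call with each library left out in turn; the calls of ULK1, LAMP1 and CTSL were lost without any 1 of the 3 sgCtrl libraries, that of NBR1 also without sgL1 6, that of MAP1LC3B with 8 of the 9 libraries left out in turn, and that of ATP6AP1 without sgCtrl 1, sgCtrl 2 or sgL1 5.

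Mitotic genes were slightly lower. Of 25 tested G2/M genes 9 fell and 0 rose (median -0.11, camera adjusted p = 1.20e-05; adjusted p = 0.114 with an estimated correlation); adjusted over the list alone, 12 fell. HMMR (-0.38), KIF23 (-0.20) and CDC20 (-0.17) kept their call with each library left out, and CENPE (-0.24) lost it without sgCtrl 2 (edgeR adjusted p = 0.0799). Of 26 G1/S genes, RRM2 (0.20), a subunit of ribonucleotide reductase, and the licensing factor CDT1 (0.18) rose and 0 fell (median 0.03, camera adjusted p = 0.288, while limma's fry test called the list higher with adjusted p = 0.00788); adjusted over the list alone, 4 rose and 1 fell, and the CDT1 call was lost without sgCtrl 2, sgCtrl 3, sgL1 3 or sgL1 5. Of 21 p53 targets, the cell cycle inhibitor CDKN1A (0.99, from 73.6 ± 5.46 to 146.4 ± 6.55 CPM), the death receptor TNFRSF10B (0.21) and BBC3 (0.50) rose and 0 fell (median 0.04, camera adjusted p = 0.0412; adjusted p = 0.1002 with an estimated correlation). Adjusted over the list alone, 4 of these rose and 1 fell; BBC3 lost its call without sgCtrl 2 (edgeR adjusted p = 0.135).

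The remaining stress and growth lists had few changed members. Of 78 cytosolic ribosomal protein genes, RPL13A (0.15) and RPL19 (0.12) rose and 0 fell (median 0.08, camera adjusted p = 0.00125; adjusted p = 0.540 with an estimated correlation), and 0 passed adjusted over the list alone; the RPL13A and RPL19 calls were lost with 5 and 6 of the 9 libraries left out in turn. Of 21 NRF2 antioxidant targets NQO1 (0.29), FTH1 (0.23) and GCLM (0.17) rose and SLC7A11 (-0.32) fell (median 0.11, camera adjusted p = 0.0412; adjusted p = 0.1002 with an estimated correlation); adjusted over the list alone, 5 rose and 1 fell, and GCLM lost its call without sgCtrl 1, sgCtrl 2, sgL1 1, sgL1 5 or sgL1 6. Of 15 heat shock genes DNAJB1 (-0.23) and HSPA8 (-0.13) fell and 0 rose (median -0.05, camera adjusted p = 0.0458; adjusted p = 0.301 with an estimated correlation), also adjusted over the list alone; HSPA8 lost its call without sgCtrl 1 or sgCtrl 2. Among 25 cholesterol synthesis genes ACAT2 (-0.17) fell (median 0.01, camera adjusted p = 0.799), and adjusted over the list alone 3 rose and 1 fell. ACAT2 lost its call without sgCtrl 1, sgCtrl 2 or sgL1 1.

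The 12 largest falls were smaller than the rises, and 11 of these genes had means under 15 CPM in sgCtrl. FAT3, an atypical cadherin (chromosome 11, 92352096 to 92896470), was the most abundant and went from 57.5 ± 3.22 CPM (SD, n = 3) to 26.9 ± 2.75 CPM (SD, n = 6), a log2 fold change of -1.10 (SE 0.07; edgeR adjusted p = 8.63e-12). PRICKLE1, a planar cell polarity gene, had -1.02, from 13.7 ± 0.975 to 6.79 ± 0.675 CPM. The others were MYPN (-1.31), VSTM2L (-1.26), C4BPB (-1.13), the axon guidance factor SEMA3E (-1.11), the phosphodiesterase PDE1C (-1.10), ANKRD30B (-1.09), TNFSF18 (-1.09), XIRP2 (-1.08), STXBP6 (-1.06) and CDK15 (-1.04). All 12 were lower in 6 of 6 sgL1 libraries, which the rule of no overlap between groups required. ANKRD30B lost its call without sgCtrl 1 (edgeR adjusted p = 0.0635).

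The 6 sgL1 libraries were not uniform. The labels do not say what the numbers 1 to 6 mark, so libraries 1-3 and 4-6 were compared as a check of the spread inside the group and not as conditions. Of 14837 genes tested, 317 were higher and 276 lower in libraries 1-3 (edgeR quasi-likelihood test, adjusted p under 0.05). UFL1 was lower in libraries 1-3 (log2 difference -0.65, SE 0.10; edgeR adjusted p = 4.06e-04) and DDRGK1 higher (0.28; edgeR adjusted p = 0.0227). SPP1 was 33.5, 31.5 and 28.9 CPM in libraries 1, 2 and 3 and 77.0, 75.2 and 74.7 CPM in libraries 4, 5 and 6 (-1.27; edgeR adjusted p = 1.16e-14). IL1B (-0.95) and IL13RA2 (-0.79) were also lower in libraries 1-3, and so were the matrix proteases MMP9 (-0.58) and MMP1 (-0.56). The sphingolipid transporter SPNS2 (0.76) was higher there; MMP1, MMP9 and SPNS2 were chosen after their values were seen and are not the largest differences. Without sgL1 4 this count of 593 genes was 43, without 6 it was 90, without 2 it was 162, without 3 it was 217 and without 1 it was 1117.

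Against sgCtrl, the calls of both sets of libraries overlapped in part. Libraries 1-3 alone gave 1195 genes higher and 1054 lower, and libraries 4-6 alone 998 and 826. Of 14620 genes tested in both, 603 rose in both, 422 fell in both and 1 went in opposite directions; independent lists would share 80.2 and 59.5. Both comparisons used the same 3 sgCtrl libraries, and simulated unchanged groups against shared controls gave 0.15 and 0.3 shared genes on average over 20 draws. The fold changes correlated across genes with r = 0.690 (covariance 0.0584), against 0.511 (covariance 0.0217) in the simulation; genes are not independent replicates, and the 3 controls could not be split, so part of the excess may come from the shared controls. Of the 1447 genes changed with all 6 libraries, 102 also differed between the sets. In camera against sgCtrl, the lysosome, p53, heat shock and immediate early lists were not called with libraries 4-6 alone, and the ribosomal, oxidative phosphorylation, epithelial and NRF2 lists not with 1-3 alone. HIF targets were slightly higher in libraries 1-3: 9 of 37 were higher and 0 lower (median difference 0.11, camera adjusted p = 9.77e-06; adjusted p = 0.188 with an estimated correlation). Glycolysis (0.10, camera adjusted p = 3.38e-05), cholesterol synthesis (0.12, 3.15e-04) and immediate early genes (0.11, 4.10e-04) were also higher by their medians and camera, and G2/M genes (-0.08, 7.55e-04) lower. Epithelial genes (0.11, camera adjusted p = 0.0168), luminal markers (0.11, 0.0184) and ATF4 targets (0.05, 0.0432) were called higher and heat shock genes lower (median -0.06, mean 0.02, adjusted p = 0.0432), and no list was called with an estimated correlation. Mitochondrially encoded transcripts, a measure of library quality, were lower in libraries 1-3 as well (median -0.17, camera adjusted p = 0.00120; adjusted p = 0.508 with an estimated correlation), and against sgCtrl they were called lower with libraries 1-3 alone (camera adjusted p = 0.0493) and not with 4-6 alone (camera adjusted p = 0.482). Among 22 NF-kB genes, IL1B, CXCL8 (-0.20) and CXCL1 (-0.16) were lower in libraries 1-3 and NFKB2 (0.23), RELB (0.28) and LIF (0.17) higher, the last 3 named after their values were seen.

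**Figure D4:**
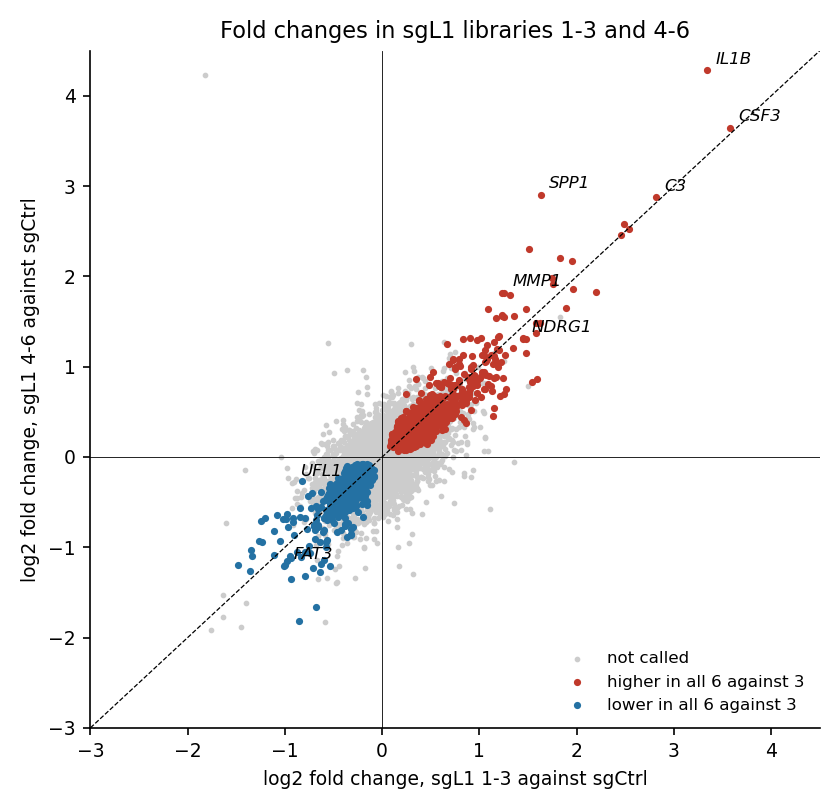
Log2 fold change against sgCtrl in sgL1 libraries 1-3 (horizontal axis) and 4-6 (vertical axis) for 13669 tested genes with a mean of at least 1 CPM; red and blue points were called higher or lower with all 6 sgL1 libraries, grey points were not, and the dashed line marks equal values. CSF3 (3.58 and 3.65) and C3 (2.81 and 2.88) lie near the line, IL1B (3.34 and 4.29) and SPP1 (1.63 and 2.91) above it.

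Most markers of fibroblasts and leukocytes were near 0, with exceptions. Of 10 fibroblast markers, COL1A2 and LUM had 0 counts in all 9 libraries, which allows at most 3 counts per library (0.195 CPM or less, counting error only), and COL1A1 and PDGFRB averaged 9.34 and 8.10 CPM in sgL1 against 7.53 and 5.09 CPM in sgCtrl, PDGFRB without overlap between the groups. Of 10 leukocyte markers, CD3E and HLA-DRA had 0 counts, CD14 averaged 1.72 and 1.57 CPM, and CD74 averaged 114.9 and 110.7 CPM. Fewer than 5 members of either list passed the count filter, so neither was tested as a list. Mitochondrially encoded transcripts took 3.55% to 3.67% of counts in sgCtrl and 3.06% to 3.67% in sgL1, lowest in sgL1 3.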

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

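No test in this part was chosen after the result was seen. Within the 6 sgL1 libraries, 8 of 145 measures, the named genes and the library measures, had 1 library so far from the others that its gap took a larger share of the group's range than Dixon's 95% critical value for 6 samples. Chance alone flags about 1 in 20, so this number is close to what chance gives. The lowest library stood apart for LAMP1 (sgL1 4, gap 0.801), UFSP1 (sgL1 4, 0.737), CCNE1 (sgL1 6, 0.695), GABARAPL1 (sgL1 5, 0.678), CSF3 (sgL1 1, 0.645) and SEMA3E (sgL1 4, 0.64). The highest library stood apart for CENPE (sgL1 4, 0.7) and RPL13A (sgL1 2, 0.688). Of these 8 measures, 4 single out sgL1 4.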

How the results depend on the processing

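The alternatives for the comparison inside sgL1, and the tallies of lists by setting and of named genes with single libraries left out, were chosen only after the result was seen. No called result changed direction under any alternative run: 141 named genes gave 3514 comparisons, of which 3100 kept their side of the threshold, 321 lost their call, 93 gained one and 0 reversed. With single libraries left out, 76 of 109 called named genes kept their call throughout. Of the 20 lists, 10 were called the same way under all 24 alternatives with camera at its preset correlation, and 0 were called the opposite way, while medians of some lists that were not called, UFMylation genes among them, changed sign; immediate early genes (12 of 24), heat shock genes and p53 targets (14 of 24 each) were called least often. The causes of the moves below were not tested unless stated.

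The 841 genes higher and 606 lower became 1307 and 1146 with 1 surrogate variable, and, because the threshold itself is stricter, 517 and 339 at an adjusted p under 0.01 and 45 and 7 when tested against a 1.5-fold change. With sgL1 1-3 only, 1054 were lower. Leaving out single libraries gave 548 to 958 higher and 352 to 800 lower, with the low counts of higher genes without sgCtrl 1 (548) and sgCtrl 2 (549) and of lower genes without sgCtrl 1 (400), 2 (352) and 3 (385), where fewer controls remain. The 20 lists became 12 at 0.01 and 5 with an estimated correlation, and lay between 14 and 19 with single libraries left out. limma's fry test called 19 lists in the same directions: it did not call ribosomal proteins (adjusted p = 0.113), oxidative phosphorylation (0.0625), immediate early genes (0.0625) or epithelial genes (0.0635), and it called G1/S (0.00788), interferon (0.0151) and MHC class I genes (0.0338), which camera did not. The 593 genes within sgL1 became 102 at 0.01 and 2 against a 1.5-fold change, and 43 to 1117 with single libraries left out: 43 without sgL1 4, 90 without 6, 162 without 2, 217 without 3 and 1117 without 1.

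UFL1 passed the threshold with limma-voom (-0.5538), no expression filter (-0.5733), sgL1 1-3 only (-0.9319), sgL1 4-6 only (-0.2842), 1 surrogate variable (-0.5911) and the replicate block given below, and without sgL1 4 (-0.6638); leaving out single libraries gave -0.6638 to -0.4968. UFM1 passed with sgL1 4-6 only (0.2194) and 1 surrogate variable (0.1718).

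Libraries with the same number in both groups did not deviate together (correlations -0.041, -0.222 and -0.029 for numbers 1, 2 and 3). No pairing by number was seen, but so few libraries cannot exclude one. With the replicate number as a block on sgL1 1-3 and sgCtrl 1-3, 1005 genes were higher and 846 lower, 16 lists were called, UFL1 passed the threshold (-0.9332) and UFM1 did not (0.1175). Gene lists were not computed for the 1.5-fold test, and the comparison within sgL1 was not run with limma-voom, FPKM or a surrogate variable. Scaling moved the median of all genes by less than 0.1 on the log2 scale, and the share of higher calls was 58.1%, 57.2%, 55.3% and 55.4% with TMM, RLE, upper-quartile and library-size factors. Changes of 1.2-fold were recovered for 38% of simulated genes at these depths, so a gene that was not called can have changed by that much.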

Other observations

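The tests of RNA from leukocytes or fibroblasts, of the lists by set of sgL1 libraries, of oxygen or density and of the UFL1 transcript level were chosen only after the result was seen, and the values of RPS18 were noted after they were seen.

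The calls of the interferon and antigen presentation lists differed between camera and fry. Of 30 tested type I interferon genes, OASL (0.40), IFIT2 (0.25), IFITM1 (0.44), IFITM3 (0.17) and ISG15 (0.20) rose and DTX3L (-0.18) fell in edgeR's test, and the list was not called by camera (adjusted p = 0.251, median 0.04), though limma's fry test called it higher (adjusted p = 0.0151); adjusted over the list alone 7 rose and 1 fell. ISG15 and DTX3L were named after their values were seen. The OASL call was lost without sgCtrl 1 (adjusted p = 0.0710), and the IFIT2, IFITM1 and IFITM3 calls without at least 4 of the 9 libraries in turn. Of 8 MHC class I genes ERAP1 (0.15), a peptide-trimming protease of the ER, rose, 0 fell and the list was not called by camera (adjusted p = 0.429) but was called higher by fry (adjusted p = 0.0338), and the ERAP1 call was lost with 8 of the 9 libraries left out in turn and with upper-quartile or library-size scaling; adjusted over the list alone 1 rose. Among 20 immediate early genes 8 rose, including JUN (0.25) and the phosphatase DUSP6 (0.21), and KLF2 (-0.44) and KLF6 (-0.21) fell (camera adjusted p = 0.0458, median 0.20; adjusted p = 0.478 with an estimated correlation), while adjusted over the list alone 10 rose and 3 fell.

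Of 11 luminal breast markers, the transcription factors SPDEF (0.62, from 16.9 ± 1.34 to 26.0 ± 3.34 CPM) and FOXA1 (0.46) rose and KRT8 (-0.21) fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.540, median 0.01). Among 13 mitochondrially encoded transcripts MT-ND6 (0.37), the 1 protein gene on the light strand, rose and MT-ATP6 (-0.44) fell, while the list was not called (camera adjusted p = 0.338, median -0.08); adjusted over the list alone 1 rose and 2 fell. Without knowledge of strand in the counting, reads of MT-ND6 cannot be separated from opposite-strand RNA. Of 10 replication-dependent histone genes HIST1H1C (0.22) rose and 0 fell (camera adjusted p = 0.583, median 0.05); its call was lost without sgCtrl 2, sgCtrl 3 or sgL1 5, and adjusted over the list alone 2 rose. Of 6 nuclear-retained RNAs 0 passed edgeR's test adjusted over all genes, which 1447 of all 15242 genes passed. Adjusted over the list alone 1 fell (camera adjusted p = 0.277, median -0.08, mean -0.004).

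RPS18, a ribosomal protein gene in the MHC region of chromosome 6 (33272010 to 33276510), had 4509 counts in sgL1 4 and 20, 26, 20, 22 and 88 counts in sgL1 1, 2, 3, 5 and 6. In sgCtrl 1, 2 and 3 it had 24, 34 and 174 counts. Its log2 fold change of 3.26 was not called (edgeR adjusted p = 0.533).

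Changed genes were counted for all 84 splits of the 9 libraries into 6 and 3. Only the real split, sgL1 against sgCtrl, gave as many as 1447 genes. The highest other split gave 297 and set sgL1 1-3 apart from the other 6 libraries, a split that follows the structure inside sgL1. The count of 1447 argues against a random labelling of 9 independent libraries. The labels do not name separate cultures, and the sgL1 libraries fell into sets, so the libraries may not be independent. A chance difference between cultures or batches therefore cannot be excluded by these splits.

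HIF targets and NF-kB genes were higher in sgL1, with list medians of 0.44 and 0.43. After removal of trends with GC content and gene length, the smaller median was 0.412, which argues against those trends as the whole cause. As a check for RNA from leukocytes or fibroblasts, 8 of their abundant transcripts together reached 0.483 CPM in sgL1 and 0.296 CPM in sgCtrl. The sum left out COL1A1, PDGFRB, CD14 and CD74, the fibroblast and leukocyte markers above 1 CPM, whose levels are given above. It therefore speaks only for the 8 transcripts. The lists were higher in both sets of sgL1 libraries, with a smallest median of 0.379, so the pattern did not rest on 1 of these sets. Both sets were compared with the same sgCtrl libraries, so these medians cannot show whether those controls were shifted. Different oxygen exposure or cell density of the dishes cannot be told apart from the genotype, since 0 libraries have a label of their own for either.

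Libraries 1-3 and 4-6 of sgL1 differed in 593 genes, and UFL1 was lower in 1-3. Of the 10 splits of 3 against 3 the real one, 1 of 10, gave the most and the highest other gave 3, but 10 splits are too few for a share under 0.05. Library depth is argued against as the cause, since libraries thinned to equal totals still gave 523 genes. Of 102 genes changed in sgL1 that also differed between the sets, 63 lay further from sgCtrl in libraries 1-3. That is the direction a graded effect of the UFL1 transcript level would give. The other 39 (38.2%), IL1B and SPP1 among them, lay further in libraries 4-6, which kept more UFL1 transcript. For these 39 genes a graded effect of that level alone is argued against. Only genes called with all 6 libraries were counted, a rule that graded genes can fail, so other genes are not covered. Different guides, clones or batches behind the numbers may explain the sets and were not tested, as the labels name none.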
